A study of Arabidopsis thaliana with 2 samples.

How the data were processed

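RNA was extracted from cotyledons of the lefko mutant and wild-type plants, both in the Col-0 background, with an on-column DNase treatment, and Illumina libraries were sequenced on a HiSeq instrument, per the labels' protocols. The labels give 1 sample per genotype. The mutant is called lefko1 in the protocol and lefko2 in the sample's title, and the source label names seeds where the protocol names cotyledons. Reads were aligned with HISAT2 version 2.0.4 to TAIR10, per the submitters' processing notes. The program that called the splicing events and its counting rule are not given in the sources used here.

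The authors deposited 5 event tables, 1 per class, and per the file headers each event has inclusion and skipping read counts for both genotypes, a p-value and an adjusted p-value (FDR). Each count cell holds 3 counts, which gives 3 count sets per genotype. All 343 listed events have an FDR under 0.05, the largest being 0.0491, so the tables hold only events past that threshold. No inclusion level and no effective length are given. Shares were compared between genotypes of the same event, since the counting rule, and with it any effect of length on a raw share, is unknown.

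The planned design assumed 1 library per genotype, and the 3 count sets per genotype were found only in the tables. The planned result was kept: events were counted by direction as the authors list them, with their FDR. Mean and SD were taken over the 3 count sets. The raw share of inclusion reads was the main measure. Within a genotype the 3 sets differed by more than counting error in a minority of events, 27.7% of 235 in wild type and 21.1% of 246 in the mutant (chi-square test, p under 0.05). Pooled over events the chi-square per degree of freedom was 3.97 and 4.02, so the sets were not counted as 1. The median p of the chi-square test was 0.209 and 0.285. The pooled values can thus rest on few events, such as NIA2, with 0, 342 and 0 skipping reads in the mutant sets. An exact permutation test of 3 against 3 sets cannot go below p = 0.1, and none was used for single events. Shares over summed reads have exact (Clopper-Pearson) 95% intervals, and a count of 0 allows up to 3 reads. Intervals and these limits cover counting error only.

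The gene identifiers in the tables matched the reference annotation (RefSeq, TAIR10.1) for 281 of 281 genes, and the sequence versions were the same. Of 1038 exon entries, 873 matched an annotated exon exactly when starts were counted from 0 and 1 when counted from 1, so 1 was added to each start. The text names genes by a rule fixed before the data were examined. Its limit of 20 reads per library was applied to each count set. It took the 8 retention events and the 4 events of each other class with the largest change in each direction, among those with at least 20 reads in each of 6 count sets, plus members of 7 fixed gene lists and genes in 3 or more classes. This named 83 events in 53 genes. Gene groups from descriptions used 9 word patterns, also fixed beforehand. Enrichment was tested with Fisher's exact test, two-sided, against 22245 nuclear protein-coding genes with an intron, with Benjamini-Hochberg adjustment.

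Retained introns were compared with 2551 annotated introns of the listed genes by length, GC content and splice site score, as the percentile of the median among 10000 random sets (seed 1). The score sums log2 odds of each base over 3 exon and 6 intron bases at the 5' site and 15 intron bases and 1 exon base at the 3' site, from all annotated introns of protein-coding genes. On simulated sets of 200 introns, one drawn from the longer side of the median reached percentile 100 and one drawn at random percentile 86.5.

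Alternatives were an FDR of at most 0.01, a change of at least 10 or 20 points, at least 20 reads in each set, distinct genes, Fisher's exact test on summed reads and the introns of all protein-coding genes as background. Alternatives added after seeing the data were limma on the log2 odds of inclusion with 0.5 added to both counts, leaving out each count set, the set number as a block, inclusion reads divided by 2, 1 event per junction, leaving out events that span several genes or share a junction with a retention event, introns that another transcript retains as background, and genes with alternative intron structures as background. Limma was tested on simulated counts for the 343 events, of which 200 were changed, with a spread of 0.15 log2 odds added between sets. It recovered 83.0% of events changed by 2 log2 odds and 60.6% of those changed by 1, and called 3 of 143 unchanged events. These rates hold for that assumed spread. Some real events spread more, such as AT1G15240, with 78, 0 and 0 skipping reads in the wild-type sets. Fisher's test on summed reads called 16 of the 143, since it ignores the spread between sets. The analysis used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, Biopython 1.88 and matplotlib 3.10.9.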

Results

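RNA of Arabidopsis thaliana cotyledons, the seed leaves, was sequenced from the lefko mutant and from its wild type, the Col-0 accession. There was 1 sample of each genotype. The deposited tables list splicing events that differed between the genotypes, with the reads that include a stretch of sequence (inclusion reads) and the reads across the junction that leaves it out (skipping reads). Each genotype has 3 sets of counts per event. The labels do not say whether the 3 sets came from separate plants, separate libraries or repeat runs, so SDs and the p-values of limma below measure only the spread between these sets. The inclusion share is inclusion reads over inclusion plus skipping reads, as a mean over 3 sets, and a change is mutant minus wild type in percentage points. Reads over the listed events summed to 166819 to 178604 per set in the mutant and 168946 to 187225 in wild type. Whole-library totals are not given in the sources used here.

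The series asks whether maturation of nuclear mRNA is disturbed in the mutant. The lists held 343 events in 281 genes, all nuclear, and the largest adjusted p among them was 0.0491 in the authors' deposited table. Inclusion was higher in the mutant in 267 events and lower in 76. Intron retention was the largest class, with 214 events in 199 genes, followed by 50 alternative 3' splice site events in 47 genes, 43 alternative 5' splice site events in 43 genes, 27 exon skipping events in 22 genes and 9 events of mutually exclusive exons in 6 genes. The median change was 19.0 points for intron retention, 21.3 for alternative 5' splice sites, 11.0 for alternative 3' splice sites, 22.2 for exon skipping and -14.8 for mutually exclusive exons, which became 5.74 without the events that span several genes (1 higher and 1 lower event left). Of the 281 genes, 257 were in 1 class, 16 in 2, 4 in 3 and 4 in 4 classes. The ranges of the 3 mutant and 3 wild-type sets did not overlap in 315 of 343 events. Chance alone would give 10%, but the events were chosen by a test on the same reads. In 98 events at least 1 set had under 20 reads.

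**Figure D1:**
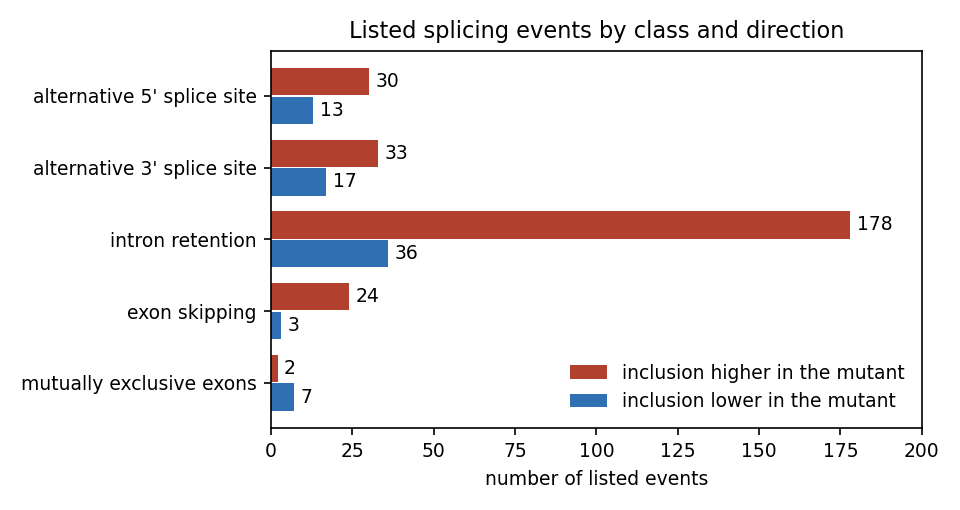
Number of listed events (x axis) in each of 5 classes (y axis), split by whether the inclusion share was higher (red) or lower (blue) in the lefko mutant than in wild type. Intron retention has 178 higher and 36 lower events, and mutually exclusive exons is the class with more lower (7) than higher (2) events.

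**Figure D2:**
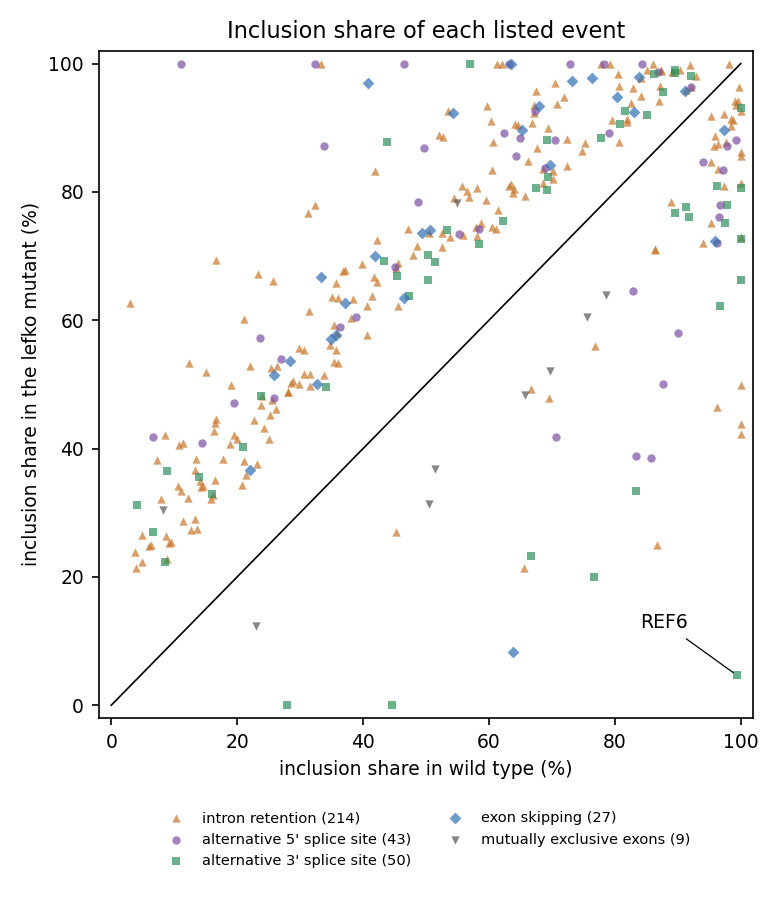
Mean inclusion share over 3 count sets in wild type (x axis, percent) against the lefko mutant (y axis, percent), 1 point per listed event, with marker shape and colour giving the class. Points above the diagonal had higher inclusion in the mutant (267 of 343), and REF6 lies in the lower right corner.

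Intron retention rose in 178 events and fell in 36. Among events with at least 20 reads in each set it rose in 143 and fell in 17. Among the latter the largest rises were in the sucrose-phosphate synthase gene ATSPS4F, by 36.9 points (SE 12.7) to 51.9% ± 19.8 (SD, 3 sets), and in AT5G38600, which encodes a proline-rich spliceosome-associated protein, from 22.0% ± 14.9 to 52.8% ± 8.30. PAT2, a gene for a vacuolar trafficking protein, went from 19.1% ± 1.62 to 49.9% ± 4.61. The ankyrin repeat gene AT5G54710 went from 37.2% ± 2.51 to 67.9% ± 0.944, with an adjusted p of 3.82e-12 in the authors' deposited table. SAMC2, which encodes an S-adenosylmethionine carrier, rose by 30.2 points, the dehydration-stress family gene AT1G69450 by 29.9 and the 5'-nucleotidase family gene AT2G23890 by 29.8. The cation-chloride cotransporter gene CCC1 went from 35.7% to 65.7% (SE of the difference 7.77 points). All 8 of these introns interrupt coding sequence. The intron of PAT2 spans 20570721 to 20570792 on chromosome 3, and that of AT5G54710 spans 22230106 to 22230358 on chromosome 5 (TAIR10.1).

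Among events with at least 20 reads in each set, retention fell most in the zinc knuckle gene AT5G20220, from 69.5% ± 5.08 to 47.8% ± 2.99, and in the casein kinase gene ckl3, from 76.9% ± 5.75 to 56.0% ± 7.24. It also fell in the kinase genes AT3G58640 (45.2% ± 5.13 to 26.9% ± 4.69) and SNRK2.10 (86.4% ± 1.16 to 71.0% ± 1.87), and in CNX2, a gene of molybdenum cofactor synthesis (97.3% ± 2.32 to 81.0% ± 7.59). These 5 introns lie in 5' untranslated regions (UTRs). AT1G28060, which encodes pre-mRNA splicing factor 3, fell by 15.3 points, the lipase family gene AT1G55280 by 13.7 and the disease resistance gene RPS6 (AT5G46470) by 12.8. The spliced junctions of these 3 genes are in no annotated transcript. By position, retention rose in 134 and fell in 7 introns within coding sequence, rose in 33 and fell in 15 in 5' UTRs, and rose in 5 and fell in 2 in 3' UTRs. In transcripts with no coding sequence 3 rose and 4 fell. Where the spliced junction was in no annotated transcript, 3 rose and 8 fell.

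Alternative 5' splice site events count reads for the longer exon, made with the downstream site, as inclusion. The longer form rose in 30 genes and fell in 13. It rose in LDA, which encodes the starch-debranching limit dextrinase, from 49.6% ± 7.87 to 86.8% ± 4.14, and in AT1G52360, which encodes a coatomer subunit, from 23.6% ± 9.69 to 57.3% ± 3.87. LDA and AT1G52360 also have listed retention events with the same start. Of the 43 events of this class, 13 share their skipping junction with a listed retention event. In those 13 the longer exon cannot be told apart from retention of the intron. The U2AF large subunit gene AT1G60900 went from 48.7% ± 4.87 to 78.4% ± 2.75, and the splicing factor gene ATO from 19.5% ± 5.38 to 47.1%, a rise of 27.6 points. The adjusted p in the authors' deposited table was 1.64e-09 for AT1G60900 and 1.35e-09 for ATO. The longer form fell in the DnaJ family gene AT5G53150, by 28.9 points (SE 5.88) to 41.8% ± 0.959, and in AT2G43760, of molybdopterin synthesis, from 82.9% ± 3.36 to 64.6% ± 1.84. AT5G51970, of the zinc-binding alcohol dehydrogenase family, was listed at 99.3% ± 1.23 and 88.1% ± 8.49, and missed the threshold of limma across the 3 sets (adjusted p 0.0530). With at least 20 reads in each set, 22 events rose and 3 fell.

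Alternative 3' splice site events count the longer exon, made with the upstream site, as inclusion. The longer form rose in 33 events and fell in 17. With at least 20 reads in each set 29 rose and 5 fell, and with a change of at least 20 points 10 rose and 10 fell. Of those 10 falls, all but that of REF6, below, had under 20 reads in at least 1 set. The largest change in any class among events with at least 20 reads in each set was a fall in REF6, which encodes a histone H3K27 demethylase. In wild type 99.4% ± 1.11 of reads used the annotated upstream site, and in the mutant 4.68% ± 3.12, a difference of -94.7 points (SE 1.91). The wild-type sets held 51, 40 and 53 reads for the upstream site and 1, 0 and 0 for the downstream site, and the mutant sets held 6, 1 and 5 against 77, 82 and 84. The sites end intron 6 of REF6 at 17938585 and at 17938595 on chromosome 3, 10 nt apart within coding sequence. The reference reads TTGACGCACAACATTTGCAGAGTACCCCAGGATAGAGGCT from 17938566 to 17938605, and both introns end in AG. The junction to the downstream site is in no annotated transcript. The longer form also fell in the glycoprotease gene GCP1 (91.8% ± 3.52 to 76.1% ± 2.37) and in ORG1 (89.5% ± 1.44 to 76.8% ± 3.61). AT1G15240, of the phox domain family, was listed at 91.2% and 77.7%, a difference of -13.5 points (SE 8.79), with an adjusted p of 0.0829 in limma across sets, and all 78 of its wild-type skipping reads came from 1 set. The longer form rose in the DNase I-like gene AT3G18500 (43.4% ± 10.6 to 69.2% ± 4.52), the RNA-binding protein genes AT3G04500 (23.7% ± 3.82 to 48.2% ± 4.96) and AT3G12640 (45.3% ± 5.04 to 66.8% ± 3.52), and the metallopeptidase gene AT3G05350 (13.9% ± 3.55 to 35.5% ± 5.39). AT3G04500 also has a listed retention event with the same start. In this class 13 of 50 events share their skipping junction with a retention event, with the same limit.

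**Figure D3:**
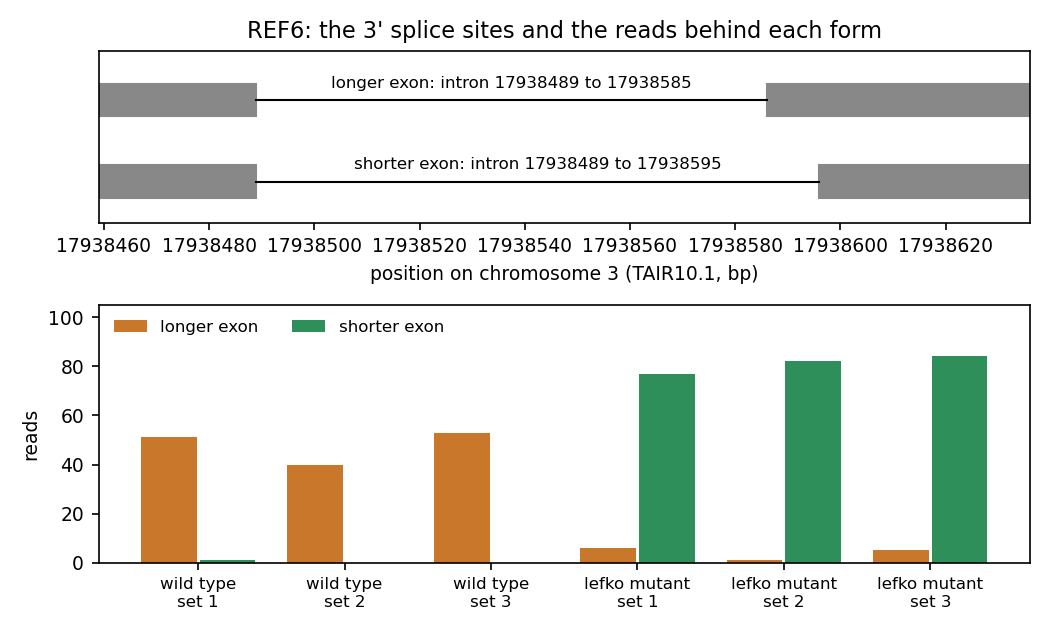
Top, the intron of REF6 drawn to scale on chromosome 3 (position in bp) with the upstream 3' splice site (longer exon) and the downstream site 10 nt further on (shorter exon), exons as grey boxes. Bottom, reads (y axis) for each form in the 3 count sets of each genotype (x axis): wild type holds 40 to 53 reads for the longer exon, and the mutant 77 to 84 for the shorter.

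Exon inclusion rose in 24 exon skipping events and fell in 3. AT2G33435, an RNA-binding protein gene, went from 41.8% ± 8.60 to 70.0% ± 5.01. In AT4G08460, of unknown function, 2 overlapping events rose by 25.6 and 25.2 points. In SR34a, an SR protein (serine/arginine-rich splicing factor) gene, 2 events rose by 25.6 and 22.2 points. PRR7, a component of the circadian clock, had 2 events, which went from 49.4% ± 4.28 to 73.6% ± 4.27 and from 35.6% ± 6.21 to 57.6% ± 2.83. Inclusion fell in AT5G40080, a mitochondrial ribosomal protein gene, from 97.3% ± 1.09 to 89.7% ± 2.73. Its skipping junction spans 6964 nt and is in no annotated transcript. Of the 120 events in the alternative splice site and exon skipping classes, 34 share their skipping junction with a listed retention event, so the classes are not independent. Among the remaining 86 events, 55 were higher in the mutant (64.0%, exact 95% interval 52.9% to 74.0%). That interval treats each event as independent. Both events of AT4G08460 share a skipping junction, however, as do both of PRR7. The higher events also include long junctions, such as that of LHCA4 (23115 nt). The share without repeated and long junctions was not tested, so an excess outside the junctions of retention events is not shown.

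In the mutually exclusive exon class 2 events had a higher and 7 a lower share in the mutant, and the tables do not say which exon is counted as inclusion. RBCS1B, a small subunit gene of Rubisco, went from 54.9% ± 1.06 to 78.2% ± 7.22, on 122364 reads in wild type and 18704 in the mutant. The share fell in CAC1, of plastid fatty acid synthesis, from 50.5% ± 4.64 to 31.4% ± 1.59. It also fell in the proteasome gene RPT6A (65.8% ± 3.85 to 48.3% ± 1.35) and in the aminopeptidase gene AT4G30910 (69.7% ± 1.05 to 52.1% ± 1.43 in the event with most change). In 7 of the 9 events, including all of these, the alternative exons lie in different annotated genes.

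Of 31 nuclear splicing factor genes in a list fixed before the data were examined, 9 were listed, with 22 events on 9 introns, and inclusion rose in all 22. The median rise was 17.1 points and the range 11.1 to 29.7. They were the SR protein genes SR30, SR34a, RS31, RS41, RS2Z32, SCL30A and SCL33, the U1 snRNP gene U1-70K and the U2AF gene AT1G60900. Retention of the intron of U1-70K (chromosome 3, 18827440 to 18828348) went from 68.5% ± 1.51 to 83.6% ± 1.38 on 5710 and 11471 reads. That of RS41 (chromosome 5, 21131187 to 21132086) went from 61.5% ± 1.66 to 77.2% ± 1.16, that of SCL33 from 63.9% ± 3.60 to 80.4% ± 1.56 and that of SR34a from 47.9% ± 3.66 to 70.1% ± 1.56. RS2Z32 rose by 19.1 points, SR30 by 12.8 and SCL30A by 13.2 in retention, and the longer form of RS31 by 11.1. In U1-70K, RS41, SCL33, SR34a, RS2Z32 and SR30 the same skipping reads also serve events of other classes. The wild-type inclusion reads of U1-70K were 1394, 1156 and 1365 for retention and 1428, 1168 and 1399 for the alternative 5' splice site. Retention of the whole intron therefore cannot be told apart here from another splice site or an exon within it. Against nuclear protein-coding genes with an intron, of which 1.23% were listed, the list was enriched 33.9-fold in odds (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p 6.37e-10 over 7 lists). Against genes with alternative intron structures annotated, which hold 6 of the 9, the odds ratio was 13.4 (adjusted p 0.000134). Both backgrounds include genes that were not expressed, since the tables hold no unlisted gene. Read depth, which affects whether an event can be listed, was not matched either, here or for the word groups below.

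**Figure D4:**
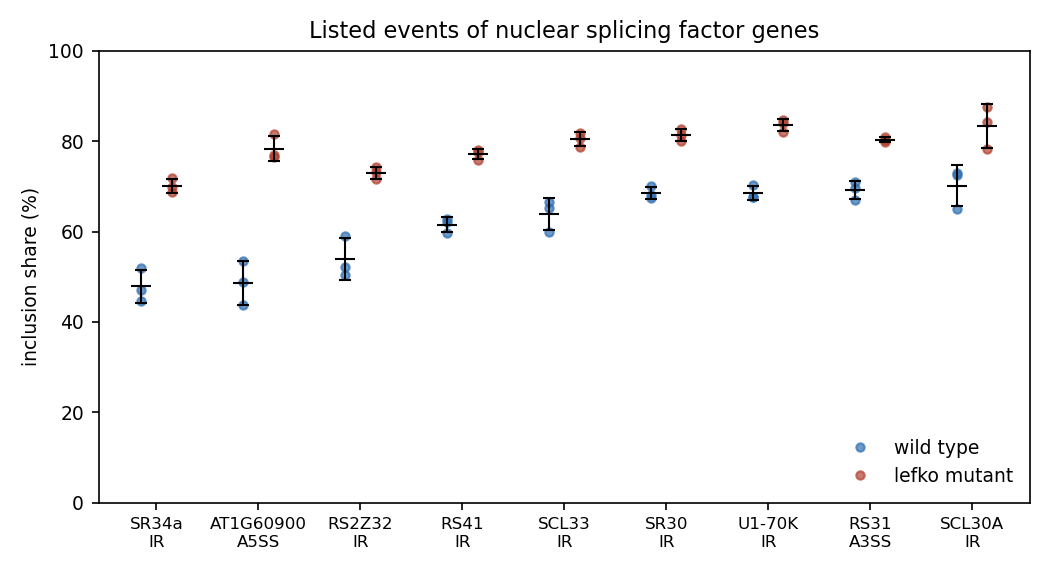
Inclusion share (y axis, percent) of 1 listed event for each of 9 nuclear splicing factor genes (x axis, with the event class, IR for intron retention, A5SS and A3SS for alternative 5' and 3' splice sites), as 3 count sets per genotype with mean and SD bars. In each gene the 3 mutant sets lie above the 3 wild-type sets, by 11.1 to 29.7 points on average.

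The other fixed lists had few members among the events. Of 12 circadian clock genes only PRR7 was listed. Of 23 nuclear genes of photosynthesis, LHCA4 and RBCS1B were listed (Fisher's exact test, adjusted p 0.0788). The LHCA4 event, at 84.4% ± 9.72 in wild type and 100% in the mutant, uses a junction of 23115 nt that reaches into other genes. The mutant's 153 reads at LHCA4 allow a skipping share of up to 1.96%. None of 13 genes of tetrapyrrole synthesis and plastid signalling, 12 chloroplast intron splicing factors, 13 chloroplast genes with introns or 4 genes of nonsense-mediated decay was listed. A list of significant events cannot show whether these genes were unchanged or too thinly covered.

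Among 9 groups defined by words in gene descriptions, splicing or RNA processing stood out, with 23 of 453 genes listed, an odds ratio of 4.59 and an adjusted p of 1.04e-07 by Fisher's exact test. Inclusion was higher in 34 of its 35 events, AT1G28060 being the exception. These events lie in 23 genes, and those of the same gene can share skipping reads, so they are not independent. The group can also hold genes of the fixed splicing factor list, so its enrichment may not be separate from that of the list. Genes of stress or defence were also enriched, with 13 of 329 listed (odds ratio 3.41, Fisher's adjusted p 0.00108), 8 events higher and 5 lower. Of 1502 kinase or phosphatase genes, 32 were listed (odds ratio 1.84, Fisher's adjusted p 0.00686), with 29 events higher and 10 lower. Transcription factors, with 9 of 1217 genes listed, and genes of ubiquitin or the proteasome, with 7 of 1052, did not pass the test (Fisher's adjusted p 0.209 and 0.202). Chloroplast (3 of 191), mitochondrial (3 of 116), pentatricopeptide repeat (1 of 134) and ribosomal or translation genes (1 of 422) did not pass it either (Fisher's adjusted p 0.576, 0.221, 1 and 0.156).

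Several genes were listed in 3 or 4 classes, and in most of them a single intron gave events in each class. SCL33, SR34a, RS41 and AT5G55100, which encodes a SWAP domain protein, rose in each. So did AT1G60200, a PWI domain splicing factor gene, whose retention went from 81.9% ± 0.705 to 91.3% ± 0.874, and the cyclin gene CYCT1;3 (91.3% ± 1.42 to 96.0% ± 0.507). In the receptor kinase gene AT4G11900, 3 events rose, with 6 to 18 reads per event in the mutant. Its other retention event, at 79.3% ± 13.8 on 90 reads and 100% on 12 reads, missed the thresholds of limma (adjusted p 0.177) and of Fisher's exact test (adjusted p 0.214). In AT5G02080, a phosphopantothenate-cysteine ligase gene, exon inclusion was 95.8% ± 7.22 and 72.4% ± 3.48 on 34 and 42 reads.

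Random sets of annotated introns of the listed genes, from which annotated retention introns were not left out, had a median length of 104 nt. The introns of the 214 retention events were longer, with a median of 157 nt. That median was at percentile 100 of 10000 random sets of equal size, whose central 95% ran from 98 to 115 nt. Introns with higher retention had a median of 162.5 nt, and those with lower retention 144 nt (percentile 97.3). With changes of at least 10 points the median was 141.5 nt (percentile 100). The background holds annotated introns whether or not they were tested, so an effect of length on being listed stays open. GC content, at 33.3%, was at percentile 67.8. The match of the 5' splice site to the average of annotated sites was at percentile 2.59, within the central 95% of random sets, and that of the 3' splice site at percentile 17.1. Against introns that another annotated transcript retains, these were at percentiles 90.5 and 98.6. The 3' splice sites of the 36 introns with lower retention were at percentile 1.28, and at 22.0 against introns that another transcript retains. Of these 36, 8 have a spliced junction in no annotated transcript, while the score and the backgrounds rest on annotated introns. Lower retention was thus not separated from annotation here. In coding sequence, 113 of the 134 introns with higher retention would add an in-frame stop codon (84.3%), against 87.9% of coding introns of the listed genes and 4645 of 6197 that another annotated transcript retains.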

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

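Fisher's exact test, the FDR limit, the limits on change and reads, distinct genes and the introns of all protein-coding genes were planned before the data were examined, and the other alternatives here were chosen after the data were seen. A length-normalized inclusion level was planned and not run, since no effective lengths are given. Intron retention stayed mostly higher in the mutant under every alternative tried, while the counts of lower events fell with stricter limits, by construction. With an FDR of at most 0.01, lower events went from 13 to 7 for alternative 5' sites, 17 to 9 for alternative 3' sites and 36 to 21 for retention, higher events from 24 to 13 for exon skipping and from 2 to 1 for mutually exclusive exons. With changes of at least 10 points, lower retention went to 22. With at least 20 points, retention went from 178 higher and 36 lower to 99 and 11, alternative 3' sites from 33 and 17 to 10 and 10, lower 5' site events to 7 and lower mutually exclusive exons from 7 to 0. Of the 10 lower 3' site events left, only REF6 had at least 20 reads in each set. With at least 20 reads in each set, lower events were 3 (5' sites), 5 (3' sites), 17 (retention) and 1 of 3 (exon skipping), higher mutually exclusive exons were 1, and the exon skipping median went from 22.2 to 19.4 points. Counted as distinct genes, lower mutually exclusive exons were 4. Without events that share a junction with a retention event, higher 5' site events went from 30 to 17. Without events spanning several genes, mutually exclusive exons kept 1 higher and 1 lower event, so their median reversed from -14.8 to 5.74, and the 5' site median went from 21.3 to 17.9. Dividing inclusion reads by 2 changed the direction of 0 events and moved the 3' site median from 11.0 to 13.9 and 46 changes of named events. In the 315 of 343 events whose sets did not overlap, neither this nor leaving out a set can change the direction. Limma across count sets passed 302 of the 343 events (247 higher, 55 lower), with lower 5' and 3' site events at 8 and 10, and 1 estimate of opposite sign, at AT4G08093. Its p-values were adjusted over these 343 listed events only. The events were chosen by a test on the same reads, so passing limma or Fisher's exact test is not independent support. Fisher's exact test passed all but 23. Leaving out single sets gave 230 to 240 higher and 48 to 55 lower limma events and turned the direction of AT4G08093 alone (without the mutant's set 3, raw share). It put the exon skipping median at 18.7 (without wild-type set 2) to 22.5. Sets with the same number did not deviate together (correlations -0.0684, -0.0766 and -0.0952), and with the replicate number as a block limma passed 241 higher and 52 lower. Among the features of retained introns, the 5' splice site percentile of 2.59 became 1.89 against introns of all protein-coding genes and 1.72 for changes of at least 10 points. For introns with lower retention, length went from 97.3 to 99.2 and GC content from 95.4 to 98.1 against all protein-coding introns. Against introns that another transcript retains, the 5' splice site percentile went from 2.59 to 90.5 for all retention events, from 5.80 to 91.9 for those higher and from 20.8 to 70.7 for those lower, and GC content of all from 67.8 to 14.8. GC content of the higher ones went from 32.5 to 78.0 against all protein-coding introns. Against introns that another transcript retains, the 3' splice site percentile went from 17.1 to 98.6 for all retention events, from 36.3 to 99.5 for those higher and from 1.28 to 22.0 for those lower. Apart from counts that fall under a stricter limit, the cause was not tested.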

Other observations

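The comparisons by intron position and by annotation of the junction, the read ratios, the long junctions and the genes named with them were chosen after the result was seen, as were the tests on REF6 and on mutually exclusive exons. Retention differed in direction by position. It was higher in the mutant in 134 of 141 listed introns within coding sequence and in 38 of 55 in UTRs (69.1%), an odds ratio of 8.56 (Fisher's exact test, two-sided, p = 3.76e-06). Among events with at least 20 reads in each set the coding introns were 113 higher and 1 lower, the UTR introns 24 and 9 (Fisher's exact test, p = 4.73e-06). Among introns with a wild-type share under 90%, 131 coding introns were higher and 0 lower, against 36 and 6 in UTRs (Fisher's exact test, p = 0.000154). Inclusion reads of the 140 higher retention events with that depth and with spliced reads in both genotypes were at a median of 2.18 times the wild-type number, and their spliced reads at 0.850 times, below 1 in 98 of 140. In the 16 lower events with that depth and with spliced reads in both, inclusion reads were at 1.02 times and spliced reads at 8.90 times. On the 9 introns of the splicing factor genes inclusion reads were at 2.30 times and spliced reads at 1.04 times. These ratios are of raw reads, uncorrected for library totals.

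Alternative splice site events with an unannotated junction were higher in the mutant, for the form without that junction, in 7 and lower in 14, against 56 and 16 where the junction is annotated (odds ratio 7, Fisher's exact test, p = 0.000324). Most of these 21 events had a wild-type share of 90% or more, with little room to rise. Among events with a wild-type share under 90% the counts were 7 and 2 against 54 and 9, and the difference did not pass the test (Fisher's exact test, p = 0.619). All but 2 of those 7 used junctions of 5000 nt or more, described below. Without such junctions, at any wild-type share, the counts were 2 and 14 against 56 and 16 (odds ratio 24.5, Fisher's exact test, p = 1.72e-06). The limit of 90% was not tested without them, so little room to rise is not shown to explain the difference. For retention the counts were 3 and 8 against 175 and 28, and 2 and 1 against 170 and 8 under 90% (Fisher's exact test, p = 3.55e-05 and 0.143). In SNM1, a DNA repair gene, the form without the unannotated junction was at 87.7% ± 4.49 in wild type and lower by 37.7 points (SE 4.12) in the mutant, on 35 and 30 reads. In SWEETIE it was at 97.4% ± 4.44 and 75.2% ± 7.73, on 43 and 73 reads. In the ARM repeat gene AT5G27970 it was at 90.1% ± 4.76 and 58.1% ± 14.9, on 41 and 61 reads.

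Junctions of 5000 nt or more appeared in 7 events, 5 of them alternative 5' splice sites, and 4 of those 5 have AT-TC ends. Outside mutually exclusive exons, all other listed skipping junctions have GT-AG, GC-AG or AT-AC ends. All 5 were higher in the mutant, so they are among the 30 rises of that class. The 5 were in AT4G21570 (87531 nt), POM1 (72532 nt), LHCA4 (23115 nt), BBD1 (22641 nt) and CNX1 (19234 nt), with 167, 188, 120, 67 and 104 junction reads in wild type and 0, 70, 0, 0 and 30 in the mutant. The other 2 were the exon skipping events of AT5G40080 (6964 nt) and AT1G58602 (13659 nt). POM1, BBD1, CNX1 and AT1G58602 missed the threshold of limma across the sets (adjusted p 0.126, 0.113, 0.0544 and 0.0521). AT4G21570, LHCA4 and AT5G40080 passed it. In the nitrate reductase gene NIA2 the listed retention share was 87.3% ± 4.25 in wild type and 98.9% ± 1.95 in the mutant, with 0, 342 and 0 spliced reads in the 3 mutant sets.

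More introns had higher than lower retention in the mutant, and genomic DNA or other uniform intron coverage in its libraries could add such reads. Uniform coverage can be no deeper than thinly covered introns, here at most 0.271 reads per nt at the 10th percentile of listed introns with reads. The excess lay above that limit in 78.7% of the higher events (140 of 178). This argues against such coverage as the whole cause only if reads along the whole intron were counted. If only reads at the intron ends were counted, reads per nt do not measure depth. The counting rule is unknown, so the test cannot decide. In the same libraries 36 introns were lower, which such coverage alone would not produce. A larger share of unprocessed RNA in the mutant's samples stays open, as does slower or less complete splicing in the lefko mutant, since the tables hold no unlisted intron to compare. Limma across the count sets passed 302 events for the real split and at most 0 for the 9 others (311 against 2 to 11 at an unadjusted p under 0.05), and of 10 splits 1, the real one, gave as many, but 10 splits are too few for a share under 0.05 and the events were listed by a test of this contrast on the same reads.

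The switch of REF6 was almost complete, and a general shift of 3' splice site choice between closely spaced sites in the mutant could produce it. Of 6 other alternative 3' splice site events with sites at most 20 nt apart and at least 20 reads in each set, 0 changed by over 50 points, and the largest change was a rise of 21.6 points, in AT3G05350. That argues against a general shift of this size, and those 6 were 2 lower, like REF6, and 4 higher, while all 18 other close events at any depth were 11 lower and 7 higher, with AT5G08480 lower by 56.7 points on 10 and 15 reads. A hypothesis is a sequence difference at the splice site in the mutant plants, which might remove the annotated site, and 0 of the deposited tables hold read sequences to test it. Other causes at REF6 in the lefko mutant stay open too.

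Changes in mutually exclusive exons may come from reads or junctions that join neighbouring copies of a duplicated gene. In 7 of the 9 events the 2 exons lie in different annotated genes, and in 6 of these they have equal lengths and 91.3% to 97.8% identical bases (RBCS1B, AT4G30910 and RPT6A), as this explanation needs. The seventh, CAC1, pairs exons with 19.1% identity with its neighbour AT5G16380. The exons of AT1G66880 and AT5G02080 each lie within 1 gene, so the explanation leaves these 2 events open. A difference in expression between the gene copies in the lefko mutant was not tested.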
